A study of Homo sapiens with 3 samples.

How the data were processed

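RNA was measured in 3 libraries of 10x Genomics Chromium 3' single-cell RNA sequencing, 1 per treatment (BMP4, CHIR and CHIR+Activin), from pooled micropatterned colonies of HES3 MIXL1:GFP cells, aimed at 10000 cells each. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.1 per the file headers, and Seurat is named in the submitters' notes for later steps. The genome build and the annotation release are not given in the sources used here, so no coordinates are given and genes carry the Ensembl IDs and symbols of the files. All 38606 genes were listed in each library, with 43 symbols used for more than 1 ID. The CHIR and CHIR+Activin matrices held 7706 and 7391 barcodes called as cells, whereas the BMP4 matrix held all 1935344 droplet barcodes.

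Cells of the BMP4 library were called as barcodes with at least 3739 UMIs, which is 10% of the 99th percentile of the top 10000 barcodes, and 9440 barcodes with 92.6% of the library's UMIs passed. Cells with fewer than 2000 genes or over 15% of UMIs from mitochondrially encoded genes were left out in all libraries, which removed 39, 622 and 515 barcodes from BMP4, CHIR and CHIR+Activin. Doublets were scored per library by the Scrublet procedure, written in Python with 2 simulated doublets per cell. Its automatic threshold marked 2, 0 and 5 cells and so did not work. The highest-scoring 6% of each library, the expected rate, were removed instead (564, 425 and 413 cells), a choice made after the data were seen.

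For each pair of libraries, UMIs were summed over kept cells and scaled by their total to CPM, and the log2 ratio was given with an exact conditional binomial interval. Genes with at least 10 CPM in either library of a pair were compared, and counts of genes at least 2-fold apart describe these libraries without a test. A library at 0 counts was set at 3 counts. Total UMIs between 117690822 and 166881797 per library put 3 counts at 0.0242, 0.0180 and 0.0255 CPM in BMP4, CHIR and CHIR+Activin. For each of 30 gene lists fixed before the data were examined, which cover cell types, signalling pathways, adhesion and matrix, cell cycle, stress and metabolism, the median log2 ratio of members with at least 10 CPM was placed as a percentile among 10000 random lists of the same size matched on expression in 20 bins, if at least 3 members were measured. Genes named in the text are a fixed panel of 36 genes, the 10 largest ratios in each direction per pair among genes of at least 50 CPM (without mitochondrial, ribosomal protein, XIST, Y-linked and clone-named genes), up to 3 members per list with the largest absolute ratios, the 5 largest ratios in each direction within a class among genes of at least 50 CPM and 2-fold, and the 10 leading genes per cluster. That rule was fixed before the data were examined.

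All 21959 cells were clustered together without integration, from log counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1. A marker counted for a cluster at 1.5-fold over the other clusters and at least 10 CPM. A cluster took the name of the class with the most such markers, with at least 3. A tie went to the class with more markers among the 10 leading genes, which decided cluster 2 alone. It was left unnamed where its 10 leading genes held more markers of another class, or where its depth was low and no marker was among them. The marker lists were fixed before the data were examined. The naming rule was set after, with 1.5-fold taken once the outcomes of 2, 1.5 and 1.3 had been seen, and the tie-break added once cluster 2 was seen to tie. Shares of cells carry exact Clopper-Pearson intervals, except that a share of 0 carries 3 cells of the total as its limit. For shares of cells with a UMI of a gene, cells were thinned to 10000 UMIs and shallower cells left out. Within a class, libraries with at least 100 cells were compared.

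The steps were tested on simulated data. Of genes simulated 4-fold and 3-fold apart, 100% and 100% were found at least 2-fold apart in every pair, 0 unchanged genes were, and the 95% intervals held the simulated ratio for 95.4%, 95.3% and 95.4% of genes in CHIR over BMP4, CHIR+Activin over BMP4 and CHIR+Activin over CHIR. A planted list reached percentile 100 in each pair. Both libraries of a pair were drawn from a shared profile with counting noise only, at the full library totals. These outcomes were therefore bound to follow. They check the calculation and say nothing about variation between libraries or cells. For 1915 simulated cells, 1800 single cells and 115 mixed pairs were drawn from 6 profiles, those of clusters 1, 2, 11, 12, 13 and 14. Clustering of the 1800 single cells alone found 6 clusters with 100% of cells beside their own profile, and doublet removal took 99.1% of the mixed pairs. Cells of a profile differed by counting noise only and the other clusters were not simulated. The real clustering, and the names and shares drawn from it, are therefore not tested by this. In the real libraries, 54.6%, 41.96% and 50.9% of the doublets simulated from BMP4, CHIR and CHIR+Activin cells scored above the removal cut, and the others would have been kept. Alternatives tried were TMM and median-of-ratios scaling, mean CPM per cell, no or a 50 CPM expression filter, looser (1000 genes, 25% mitochondrial) and stricter (3000 genes, 10%) cell filters, doublets kept, a BMP4 floor of 503 UMIs, resolutions of 0.5 and 2, 50 principal components, thinning before clustering, naming at 2-fold or 1.3-fold or without the tie-break, cluster 6 alone for the epiblast-like class, and for detection no thinning, 5000 UMIs or at least 2 UMIs. Tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.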

Results

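Single-cell RNA was counted in micropatterned colonies of HES3 cells, an established human embryonic stem cell line, carrying a green fluorescent protein reporter at MIXL1. Colonies, with 10 µM of Y27632 listed for every library, were grown for 24 h and then treated for 48 h in 1 of 3 ways. The BMP4 arm received 50 ng/mL of BMP4, a ligand of the BMP pathway. The CHIR arm received 6 µM of CHIR99021, an inhibitor of GSK3 that activates WNT signalling. The CHIR+Activin arm received 3 µM of CHIR99021 with 100 ng/mL of Activin A, a ligand that acts through the NODAL receptors. Each arm was 1 library of about 10 pooled micropatterns, so no replicate check was possible and no test between treatments was made. After filtering, 8837 BMP4 cells, 6659 CHIR cells and 6463 CHIR+Activin cells were kept, with 123795142, 166881797 and 117690822 UMIs. Median depth per cell was 12327, 22295 and 16790 UMIs, with 4438, 6205 and 5240 genes detected. Gene levels are in CPM, a gene's counts summed over the kept cells of a library and scaled by the library's total. Intervals are exact 95% intervals and cover counting error only.

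The colonies held different mixtures of cell types under the 3 treatments. In the BMP4 library, 34.6% (33.6 to 35.6) of cells were mesoderm-like, meaning that they carried markers of nascent mesoderm such as MESP1, TBX6 and APLNR. The same cluster held 0 of 6659 cells (a count of 0 allows up to 0.0451%) in the CHIR library and 0.851% (0.642 to 1.11) in the CHIR+Activin library. Amnion-like cells, with GATA3, TFAP2A and ISL1, made up 8.18% (7.62 to 8.77) of the BMP4 library, 0.120% (0.0519 to 0.237) of the CHIR library and 0.0155% (0.000392 to 0.0862) of the CHIR+Activin library. The last 2 shares rest on 8 cells and 1 cell and were 0% at resolution 2, with 50 principal components, with the stricter cell filter and with cells thinned before clustering. Endoderm-like cells, in a cluster named for SOX17, CER1 and FOXA2 among its markers, made up 1.301% (1.08 to 1.56) of BMP4, 0.345% (0.219 to 0.518) of CHIR and 4.95% (4.44 to 5.51) of CHIR+Activin cells.

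These shares came from 15 clusters of all 21959 cells. Epiblast-like cells, in clusters 6, 8 and 13, made up 8.02% (7.46 to 8.61) of BMP4, 19.04% (18.1 to 20.01) of CHIR and 23.95% (22.9 to 25.01) of CHIR+Activin cells. Cluster 6 was named for SOX2, USP44, SFRP2, TERF1 and DPPA2, cluster 8 for USP44, ESRG, TERF1 and DPPA2, and cluster 13 for 10 markers, SOX2 among them. SOX2 did not pass in cluster 8, and NANOG and POU5F1 passed in none of these clusters. Neither cluster 8 nor cluster 13 had an epiblast marker among its 10 leading genes. Streak-like cells, in clusters 2 (named for TBXT, MIXL1, EOMES, FGF4 and WNT3), 4 (MIXL1, EOMES, FGF8 and FGF4) and 7 (FGF8, FGF4, NODAL and SP5), made up 33.8% (32.8 to 34.8), 20.3% (19.3 to 21.3) and 31.4% (30.2 to 32.5). The streak-like BMP4 cells lay almost wholly in cluster 2 (2808 cells), which held 0 CHIR and 9 CHIR+Activin cells, whereas those of the other libraries lay in clusters 4 and 7. Cluster 2 had equal numbers of streak and caudal markers (5 each) and took the streak name through a tie-break added after this tie was seen. Without the tie-break, the streak-like share of BMP4 was 2.01%. Over all settings the streak-like shares ranged from 0% to 34.2% in BMP4, 0% to 23.6% in CHIR and 0% to 31.4% in CHIR+Activin. The epiblast-like shares ranged from 0% to 12.8%, 0% to 64.3% and 0% to 57.8%, so no order of the libraries is read from either class. Clusters 1, 2, 11 and 12 were almost wholly from the BMP4 library, and with 1 library per treatment such a cluster can be that library and not a type.

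Cluster 11 held 8.97% (8.39 to 9.59) of BMP4 cells, 0 of 6659 cells (a count of 0 allows up to 0.0451%) in CHIR and 0 of 6463 cells (a count of 0 allows up to 0.0464%) in CHIR+Activin. More primordial germ cell markers than markers of any other class passed in it, but it was left unnamed because its leading genes held more markers of other classes (PRDM1, SOX17 and TFAP2C). Clusters 3, 5, 9, 10 and 15 also carried no name and together held 5.10% (4.65 to 5.58) of BMP4, 60.2% (59.02 to 61.4) of CHIR and 38.9% (37.7 to 40.1) of CHIR+Activin cells. Cluster 3 held 1.98%, 15.4% and 16.1% of BMP4, CHIR and CHIR+Activin cells, and cluster 5 held 1.23%, 14.97% and 10.8%. In the same order, cluster 9 held 0.373%, 14.99% and 4.98%, cluster 10 held 0.260%, 13.6% and 5.88%, and cluster 15 held 1.26%, 1.20% and 1.11%. In cluster 3 the epiblast markers SOX2 and USP44 passed, and in cluster 5 NANOG and SOX2, fewer than the 3 needed for a name. The streak marker FGF8 passed in both. In cluster 9 the endoderm marker FOXA2 passed, and in cluster 10 FOXA2 and HHEX, with the epiblast marker ESRG. The threshold that left these clusters unnamed, 1.5-fold, was chosen among 3 (2, 1.5 and 1.3) whose outcomes had been seen. No cluster took the endoderm name at a clustering resolution of 0.5, with the stricter cell filter or with the 1.3-fold threshold, and the endoderm-like shares of BMP4, CHIR and CHIR+Activin were 1.74%, 2.23% and 11.45% when cells were thinned before clustering, so the order of BMP4 and CHIR turned and is not read. In cluster 14 a SOX17 UMI was found in 91 of 115 BMP4, 4 of 23 CHIR and 131 of 320 CHIR+Activin cells, and a FOXA2 UMI in 14 of 115, 18 of 23 and 166 of 320, so most CHIR and most CHIR+Activin cells counted as endoderm-like had no SOX17 UMI.

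**Figure D1:**
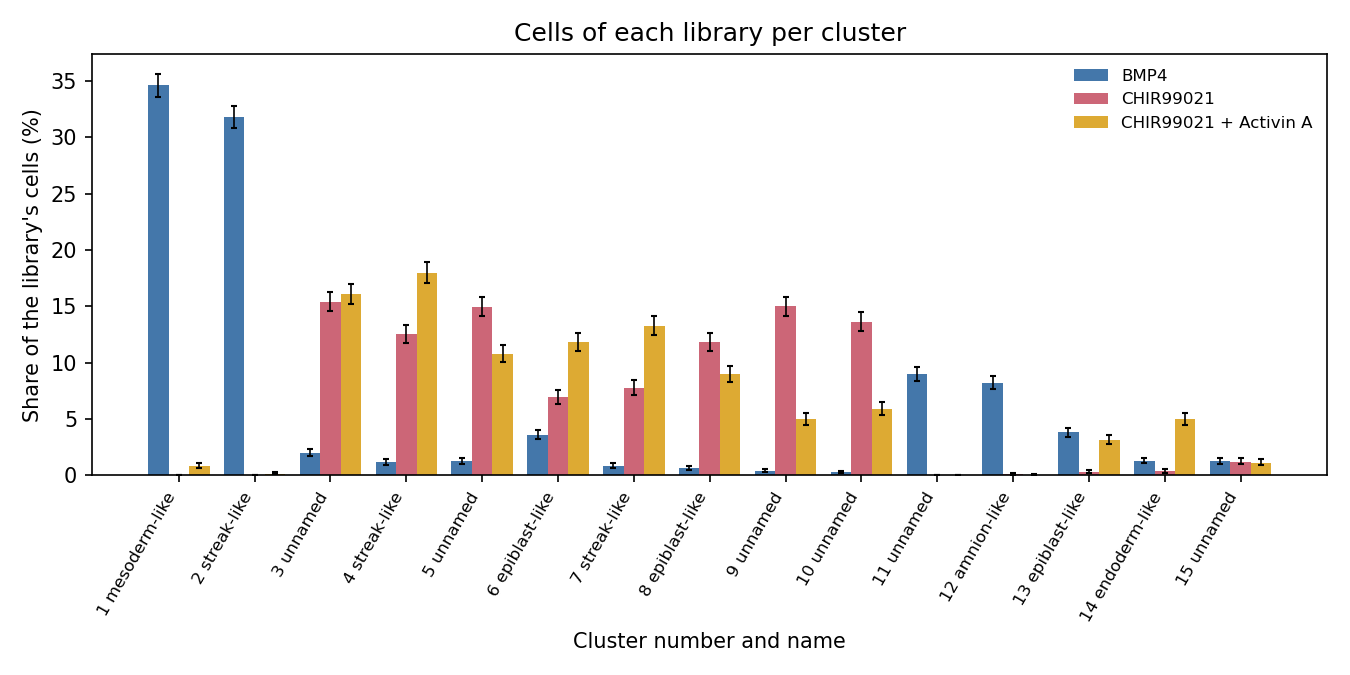
Share of each library's kept cells (percent, vertical axis) in each of the 15 clusters (horizontal axis), with bars for the BMP4, CHIR and CHIR+Activin libraries and exact 95% intervals for counting error. Cluster 1, mesoderm-like, held 34.6% of BMP4 cells and 0.851% of CHIR+Activin cells, and cluster 14, endoderm-like, held 1.301%, 0.345% and 4.95% of BMP4, CHIR and CHIR+Activin cells.

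The comparison of CHIR with BMP4 asked how colonies under direct WNT activation differed from colonies under BMP4. Mesoderm and amnion genes were far lower under CHIR. MESP1 (ENSG00000166823), a transcription factor of nascent mesoderm, stood at 0.713 CPM under CHIR and 243 CPM under BMP4, 341-fold lower. HAND1 (ENSG00000113196), a regulator of lateral and extraembryonic mesoderm, stood at 0.120 against 129 CPM, and GATA3 (ENSG00000107485), a factor of amnion and trophoblast, at 0.264 against 27.02 CPM. Pluripotency genes were higher under CHIR, with SOX2 (ENSG00000181449) at 71.5 against 24.4 CPM and NANOG (ENSG00000111704) at 72.4 against 30.8 CPM. The endoderm factors SOX17 (ENSG00000164736) and FOXA2 (ENSG00000125798) went opposite ways, SOX17 at 0.132 against 52.7 CPM and FOXA2 at 54.8 against 2.96 CPM. Endoderm-like cluster 14 held only 64 of the 9145 CHIR UMIs of FOXA2. FOXA2 was a leading gene of streak-like cluster 4 and unnamed cluster 9, so its level does not stand for endoderm-like cells of CHIR.

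Of 10113 genes with at least 10 CPM in CHIR or BMP4, 282 were at least 2-fold higher under CHIR and 307 at least 2-fold lower. At least 4-fold, the counts were 29 higher and 140 lower. Among genes of at least 50 CPM, the 10 with the largest ratios toward CHIR began with FOXA2 (log2 ratio 4.21, interval 4.06 to 4.37), the stress-induced mTORC1 inhibitor DDIT4 (2.99, interval 2.94 to 3.04) and the streak growth factor FGF8 (2.86, interval 2.77 to 2.94). PRUNE2 (2.18), VLDLR-AS1 (2.15), LEFTY1, an inhibitor of NODAL (2.01), FRMPD4 (2.0), ACOXL (1.99), ADAMTS20 (1.89) and SESN2, a stress-induced sestrin (1.88), completed them. FOXA2, DDIT4, PRUNE2, VLDLR-AS1, ADAMTS20 and SESN2 were leading genes of cluster 8, 9 or 10. These 3 clusters held 788, 998 and 907 CHIR but 54, 33 and 23 BMP4 cells. Without these clusters, 218 genes were at least 2-fold higher under CHIR, 199 of them among the 282. At least 2-fold lower were 318, with 289 of them among the 307. Toward BMP4, HAND1 led at -10.08 (interval -10.79 to -9.45, from 20 CHIR UMIs), followed by SOX17 at -8.64 (interval -9.32 to -8.04, from 22 CHIR UMIs) and MESP1 at -8.41 (interval -8.68 to -8.15). The remainder were the T-box factor TBX3 (-6.89), HPGD, which degrades prostaglandins (-6.80), the BMP target MSX2 (-6.19), the matrix link protein HAPLN1 (-5.87), the ligand WNT5A (-5.75), the BMP-binding protein BMPER (-5.26) and PCAT14 (-4.90). Of the 22 CHIR UMIs of SOX17, 21 came from 4 cells, and the interval of SOX17 does not cover such differences between cells.

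Among cell type lists, all 10 measured members of nascent and paraxial mesoderm were at least 2-fold lower under CHIR, with a median log2 ratio of -4.49, at percentile 0 of 10000 random lists matched on expression. FOXC1 (-6.35) and RSPO3 (-5.99) followed MESP1. All 6 measured amnion or trophoblast members were at least 2-fold lower (median -4.01, percentile 0), with TFAP2A at -7.27, GATA3 at -6.68 and ISL1 at -5.59. Of 7 caudal epiblast or neuromesodermal members, 6 were at least 2-fold lower (median -2.68, percentile 0), among them CDX2 (-4.21), EVX1 (-3.55) and the retinoic acid hydroxylase CYP26A1 (-3.01). Definitive endoderm, with 5 members measured, had a median of -2.13 (percentile 0), 1 member at least 2-fold higher (FOXA2) and 3 lower, PRDM1 at -4.17 among them. These members do not stand for endoderm-like cells of BMP4, since cluster 11 held 54.5% of the BMP4 UMIs of SOX17 and 66.6% of those of PRDM1, mesoderm-like cluster 1 held 75.6% of those of CER1, and cluster 14 held 14.04%, 3.43% and 8.60%. Pluripotent epiblast genes had a median of 0.50 (percentile 100) over 16 members, 5 of them at least 2-fold higher, including SOX2 (1.55), NANOG (1.23) and USP44 (1.16). POU5F1, which marks pluripotent and early germ layer cells, stood at 1043 under CHIR and 898 CPM under BMP4. The primitive streak list was split, with 4 of 12 members at least 2-fold higher, 2 at least 2-fold lower and a median of -0.22 (percentile 0.23). FGF8 was higher, whereas LHX1 (-4.66) and TBXT, the brachyury factor of the streak (-2.07, 47.6 against 201 CPM), were lower. MIXL1 (ENSG00000185155), the homeobox gene that the line reports, stood at 171 CPM under CHIR and 281 CPM under BMP4, and EOMES, a T-box factor of streak and endoderm, at 80.6 and 153 CPM.

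Among signalling lists, BMP target genes were lower under CHIR (7 of 8 at least 2-fold, median -2.14, percentile 0), led by MSX2, ID4 (-4.0) and ID1 (-2.71, 135 against 879 CPM). WNT feedback and beta-catenin target genes had a median of -0.84 (percentile 0) over 12 members, 5 at least 2-fold lower and 1 higher. LGR5 (-5.69), NOTUM (-2.80), BAMBI (-2.65) and LEF1 (-1.08) were lower, whereas AXIN2, a feedback inhibitor of WNT signalling, was higher (0.63). BAMBI is a member of the BMP target list as well. NODAL and Activin target genes had a median of 0.02 (percentile 49.3), with LEFTY1 and LEFTY2 (1.58) higher and CER1, a secreted inhibitor of NODAL, BMP and WNT, lower (-2.13). NODAL itself stood at 178 under CHIR and 86.97 CPM under BMP4, WNT3 at 62.9 and 88.8 CPM, and the BMP4 gene at 2.57 and 45.6 CPM. NOTCH pathway target genes had a median of 0.92 (percentile 99.89) over 5 members, with HES6 (1.60) and NRARP (1.32) higher and DLL3 lower (-1.45). FGF and ERK target genes had a median of 0.17 (percentile 88.4), SPRY1 being 1.03.

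Mesenchymal and EMT genes were lower under CHIR (6 of 9 at least 2-fold, median -1.48, percentile 0), with the EMT factors ZEB2 (-3.26) and SNAI1 (-2.16) and the cadherin CDH11 (-1.96). Extracellular matrix genes had a median of 0.09 (percentile 80.1), while 5 of 15 were at least 2-fold lower, including the collagens COL5A1 (-2.82) and COL5A2 (-2.74). Keratin genes had a median of -0.79 (percentile 0.11), with KRT19 at -1.09. Epithelial adhesion genes had a median of 0.14 (percentile 88.6), with OCLN at 1.08. Glycolysis genes were higher under CHIR (median 0.60, percentile 100, 3 of 17 at least 2-fold), including the lactate transporter SLC16A3 (1.23). Cholesterol synthesis genes (median 0.45, percentile 100, INSIG1 0.92), unfolded protein and integrated stress genes (0.40, percentile 99.93, CHAC1 2.74), p53 and apoptosis genes (0.53, percentile 99.96, PMAIP1 0.65) and mitochondrially encoded genes (0.19, percentile 99.595) also had positive medians. The integrated stress list was also higher within cluster 4 (0.46) and cluster 6 (0.36), so it did not rest on clusters 8, 9 and 10 alone. How far those clusters carry the glycolysis median of this pair is not given here. The dissociation and stress list had a median of 0.02 (percentile 45.25), with ATF3 at 1.83. Neither the S phase (-0.08, percentile 1.82) nor the G2/M phase list (-0.16, percentile 0) had a member at least 2-fold apart.

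Some lists had fewer than the 3 measured members that a median needed. Of the lateral, cardiac or extraembryonic mesoderm list 2 of 19 genes were measured in this pair, with GATA4 at -1.79, and of the axial mesoderm list 1 of 9, GSC at -0.38. The primordial germ cell list had 2 of 9 (KIT 0.62, PDPN -0.26), the haemato-endothelial list 2 of 12 (KDR -0.38, EGFL7 0.14) and the retinoic acid list 2 of 10 (CRABP2 0.18). Neural ectoderm had 0 of 13 and the HOX genes 0 of 27, and the same was true of the other pairs. The neural factor PAX6 had 3, 16 and 2 UMIs in the BMP4, CHIR and CHIR+Activin libraries, and SOX1 had 1, 1 and 0, a count of 0 allowing up to 0.0255 CPM. MSGN1, a factor of presomitic mesoderm, had 1082, 3 and 12 UMIs. The node genes CHRD (0.501, 0.431 and 0.425 CPM) and NOTO (0.258, 0.168 and 0.161 CPM) stayed under 1 CPM in every library. LEFTY1 and LEFTY2 are near-identical paralogs, as are HSPA1A and HSPA1B, and strand use in the counting of antisense transcripts such as VLDLR-AS1 is not given in the sources used here, so the levels of these genes are uncertain to that extent.

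The comparison of CHIR+Activin with BMP4 asked the same of colonies under WNT activation with added Activin. Mesoderm and amnion genes were again lower than under BMP4. MESP1 stood at 4.89 CPM, 49.7-fold lower than under BMP4, HAND1 at 1.25 CPM, 104-fold lower, and the amnion factor TFAP2A at 0.153 CPM, 205-fold lower. The NODAL inhibitors LEFTY2 (128 CPM, 5.01-fold) and LEFTY1 (152 CPM, 4.72-fold), the pluripotency factor SOX2 (85.4 CPM, 3.50-fold) and the endoderm factor FOXA2 (40.3 CPM, 13.6-fold) were higher. SOX17 stood at 9.12 CPM, 5.79-fold lower than under BMP4, and GATA6, a factor of endoderm and mesoderm, at 57.4 CPM, 4.09-fold lower.

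Of 9954 genes compared, 183 were at least 2-fold higher under CHIR+Activin and 282 at least 2-fold lower than under BMP4, and 15 and 118 at least 4-fold. Highest by ratio among genes of at least 50 CPM were FGF8 (log2 ratio 2.81, interval 2.72 to 2.90), LEFTY2 (2.32, interval 2.27 to 2.38) and LEFTY1 (2.24, interval 2.19 to 2.29). DDIT4 (2.23), ACOXL (2.07), FRMPD4 (1.92), KIAA0825 (1.87), SOX2 (1.81), the cell adhesion molecule DSCAM (1.67) and the antisense transcript GP6-AS1 (2.78-fold) came next. Lowest were HAND1 (-6.69, interval -6.94 to -6.46), TBX3 (-6.05, interval -6.31 to -5.81) and MESP1 (-5.64, interval -5.76 to -5.52). MSX2 (-5.44), HAPLN1 (-5.34), HPGD (-5.31), BMPER (-4.57), the neuropeptide gene NTS (-4.16, 66.7 against 1191 CPM), WNT5A (-4.01) and PCAT14 (-3.92) followed.

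All 10 measured nascent and paraxial mesoderm genes were at least 2-fold lower (median -3.22, percentile 0), with MESP2 at -5.20 and RSPO3 at -4.29. So were 5 of 6 amnion or trophoblast genes (median -3.85, percentile 0), with GATA3 at -7.46 and ISL1 at -5.23, and 5 of 7 caudal genes (median -1.66, percentile 0), with CDX2 at -4.74, EVX1 at -3.06 and WNT8A at -2.49. Definitive endoderm genes had a median of -0.58 (percentile 0.16) over 5 members, with FOXA2 at 3.77, SOX17 at -2.53 and PRDM1 at -2.25, the last 2 carried in BMP4 mostly by cluster 11. Pluripotent epiblast genes had a median of 0.49 (percentile 100), with 5 of 16 at least 2-fold higher, including the TGF-beta family ligand GDF3 (1.39) and USP44 (1.18). The primitive streak list had 2 members at least 2-fold higher and 2 lower (median -0.22, percentile 0.15), the latter LHX1 (-1.99) and TBXT (-1.96). MIXL1 stood at 176 and EOMES at 96.2 CPM, with log2 ratios of -0.67 and -0.67 to BMP4.

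BMP target genes were lower (7 of 8 at least 2-fold, median -1.86, percentile 0), with ID4 at -3.76 and ID1 at -2.16. WNT feedback and beta-catenin target genes had a median of -0.92 (percentile 0), with 5 of 11 at least 2-fold lower, including LGR5 (-2.85), BAMBI (-2.36), NOTUM (-2.01) and LEF1 (-1.82), and AXIN2 at 0.50. NODAL and Activin target genes had a median of 0.02 (percentile 68.4) with 4 of 11 at least 2-fold higher and 0 lower. The FGF and ERK (-0.06, percentile 25.75) and NOTCH pathway (0.28, percentile 96.01) lists lay inside the central 95% of random lists. Mesenchymal and EMT genes were lower (6 of 9 at least 2-fold, median -1.51, percentile 0), with ZEB2 at -2.75 and CDH11 at -2.60, as were extracellular matrix genes (-0.25, percentile 0.04), with fibronectin, FN1, at -2.11, and keratin genes (-0.62, percentile 0.1).

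Glycolysis (0.49, percentile 100), cholesterol synthesis (0.41, percentile 100), p53 and apoptosis (0.40, percentile 99.98), unfolded protein and integrated stress (0.21, percentile 99.3) and mitochondrially encoded genes (0.19, percentile 99.795) had positive medians, with HK2, a hexokinase, at 0.77, SESN2 at 1.21 and CHAC1 at 2.09. The G2/M phase list had a median of -0.14 (percentile 0). Epithelial adhesion (0.02, percentile 67.9), S phase (-0.06, percentile 8.46) and dissociation and stress genes (-0.11, percentile 7.405) lay inside the central 95% of random lists. Among lists too small for a median, GATA4 stood at -1.30, GSC at 0.17, KIT at 0.46, PDPN at -0.15, KDR at -0.28, EGFL7 at 0.19, CYP26A1 at -1.66 and CRABP2 at -0.28.

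**Figure D2:**
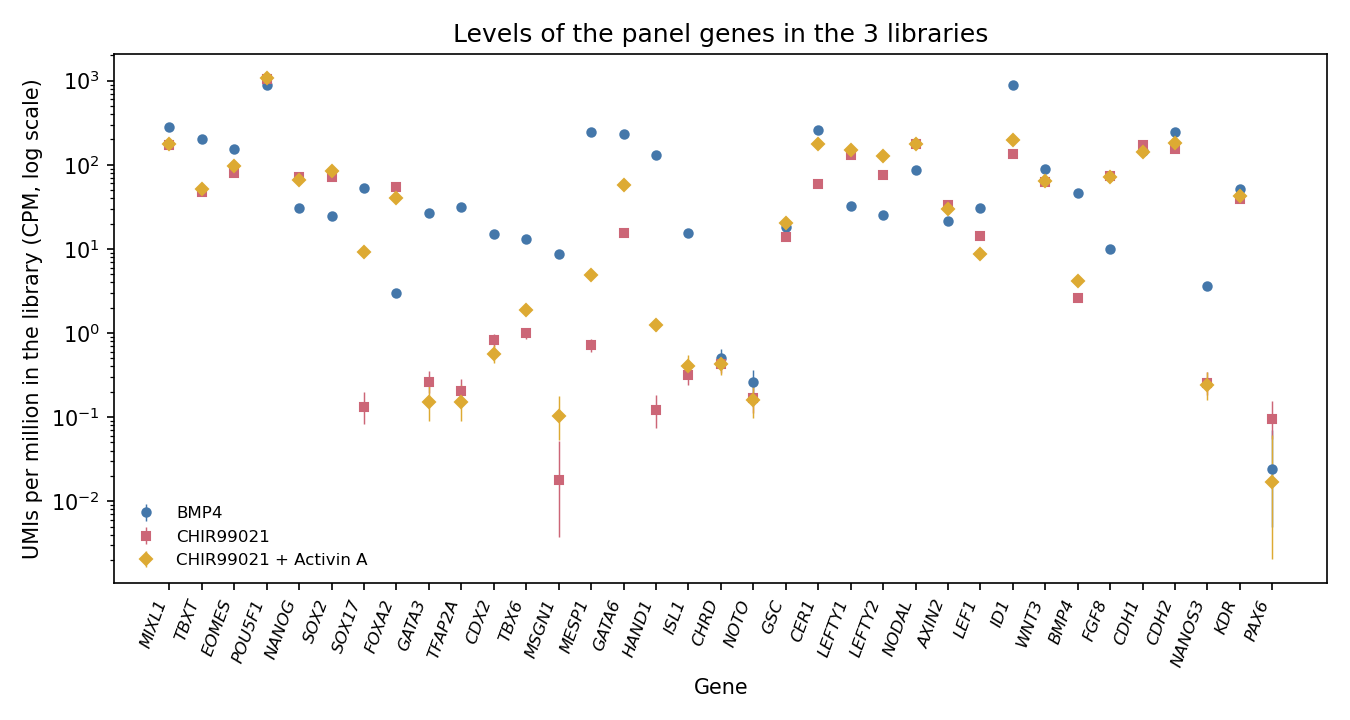
Level of each panel gene with at least 1 UMI in every library, in CPM on a log axis, with points for the BMP4, CHIR and CHIR+Activin libraries and exact 95% Poisson intervals for counting error. MESP1 lay at 243, 0.713 and 4.89 CPM, SOX17 at 52.7, 0.132 and 9.12 CPM, and POU5F1 at 898, 1043 and 1069 CPM under BMP4, CHIR and CHIR+Activin.

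The comparison of CHIR+Activin with CHIR asked how colonies with Activin added differed from those under WNT activation alone, although the dose of CHIR99021 differed as well (3 against 6 µM). The 2 libraries were close. SOX17 (9.12 against 0.132 CPM), GATA6 (57.4 against 15.4 CPM) and CER1 (174 against 59.3 CPM) were higher with Activin, whereas FOXA2 was lower (40.3 against 54.8 CPM). The definitive endoderm list lay inside the central 95% of random lists (median log2 ratio 0.10, percentile 96.7). That median rested on 3 of 12 members, CER1, FOXA2 and FOXA3. SOX17 did not pass the expression filter in either library, so the median does not include its rise. Also higher with Activin were the growth factor gene FGF17 (125 against 31.5 CPM) and LHX1, a factor of streak and endoderm (31.5 against 4.96 CPM). Cluster 14, with 4.95% of CHIR+Activin and 0.345% of CHIR cells, held 1043 of 1073 SOX17 UMIs in CHIR+Activin and 21 of 22 in CHIR. Of the CER1 UMIs it held 9453 of 20508 and 667 of 9892. The rise of SOX17 thus goes with a larger share of that cluster. For CER1 this holds only in part, since most of its UMIs lay outside cluster 14 in both libraries. FGF17 was also higher within the streak-like class (177 against 87.9 CPM), which does not hold cluster 14. How far GATA6 and LHX1 rest on cluster 14 is not given here. The stress-response genes DDIT4 (142 against 241 CPM) and SESN2 (31.9 against 50.9 CPM) were lower, by under 2-fold. The dissociation and stress list and the p53 and apoptosis list lay inside the central 95% of random lists.

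Of 9815 genes compared, 18 were at least 2-fold higher with Activin and 3 at least 2-fold lower. The 3 lower genes, named after their values were seen, were LINC02320 (log2 ratio -1.27), ENSG00000228033 (-1.055) and PNMA2 (-1.0). Among genes of at least 50 CPM, DSCAM (2.18, interval 2.11 to 2.26), FGF17 (1.99, interval 1.94 to 2.04), GATA6 (1.90, interval 1.84 to 1.97) and CER1 (1.56, interval 1.52 to 1.59) had the largest ratios. LINC02955 (0.94), the hyaluronan synthase HAS2 (0.92), LINC00458 (0.75), LEFTY2 (0.75), LRFN5 (0.72) and NTS (0.71) followed at under 2-fold. The 10 lowest were all within 2-fold: DDIT4 (-0.77), VLDLR-AS1 (-0.76), the cystine transporter SLC7A11 (-0.69), ESYT2 (-0.68), SESN2 (-0.67), MACC1 (-0.61), MIR325HG (-0.57), ADAMTS20 (-0.54), DYNC2I1 (-0.53) and GMDS-DT (-0.52). With the libraries scaled by total counts, 85.7% of the genes at least 2-fold apart were higher with Activin, and under TMM or median-of-ratios scaling 95.8% were (23 higher and 1 lower in each).

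NODAL and Activin target genes had a median log2 ratio of 0.17 (percentile 100) over 11 members, with 1 at least 2-fold higher (CER1). NODAL itself stood at 179 and 178 CPM, and LEFTY1 at 152 and 129 CPM. BMP target genes had a median of 0.23 (percentile 99.99) over 6 members, with ID1 at 0.54 and SMAD6 at 0.29. The caudal list, with 3 members measured, had a median of 1.35 (percentile 99.995), carried by FGF17 and CYP26A1 (1.35), with NKX1-2 at -0.25, and its median was -0.095 with no expression filter. Definitive endoderm genes, 3 measured, had a median of 0.10 (percentile 96.7), with CER1 higher, FOXA3 at 0.10 and FOXA2 at -0.44 (40.3 against 54.8 CPM). The primitive streak list had a median of 0.02 (percentile 93.75), with LHX1 at 2.66, FGF4 at 0.40, FST, an inhibitor of Activin, at -0.29, TBXT at 0.12, MIXL1 at 0.05 and EOMES at 0.25. Pluripotent epiblast genes had a median of 0.05 (percentile 94.4), with SOX2 at 0.26 and POU5F1 at 0.04.

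Unfolded protein and integrated stress genes were lower with Activin as a list (-0.29, percentile 0), with SESN2, CHAC1 (-0.65) and the serine synthesis enzyme PSAT1 (-0.42), though none of 9 was 2-fold apart. Glycolysis genes were lower as a list (-0.14, percentile 0), with ENO2 at -0.51 and SLC16A3 at -0.51, but had a median of 0.069 without the cells of clusters 8, 9 and 10. FGF and ERK (-0.14, percentile 2.185), NOTCH pathway (-0.21, percentile 2.36) and epithelial adhesion genes (-0.15, percentile 0.49) had low medians, with DUSP6 at -0.48, HES1 at -0.35 and the epithelial cadherin CDH1 at -0.30. Keratin (0.17, percentile 99.07) and G2/M phase genes (0.03, percentile 99.95) had high ones. WNT feedback and beta-catenin target genes (-0.13, percentile 8.35) held DKK1, a secreted WNT inhibitor, at 1.0 and LEF1 at -0.74. Lists inside the central 95% of random lists were mesenchymal and EMT (0.01, percentile 79.0), extracellular matrix (-0.12, percentile 3.19), S phase (-0.01, percentile 94.8), p53 and apoptosis (-0.08, percentile 26.2), dissociation and stress (-0.01, percentile 80.7), mitochondrially encoded (0.00, percentile 18.2) and cholesterol synthesis genes (-0.04, percentile 42.01). Nascent and paraxial mesoderm and amnion or trophoblast each had 2 members measured, with DLL3 at 0.23, SNAI1 at 0.03, TFAP2C at 0.30 and KRT19 at 0.20. In the other small lists GATA4 stood at 0.49, GSC at 0.55, KIT at -0.17, PDPN at 0.11, KDR at 0.10, EGFL7 at 0.05 and CRABP2 at -0.46.

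Within the endoderm-like class (cluster 14), 320 CHIR+Activin cells were compared with 115 BMP4 cells. FOXA2 was higher in the CHIR+Activin cells (65.5 against 13.4 CPM, log2 ratio 2.29, interval 1.63 to 3.04), whereas SOX17 was lower (175 against 645 CPM, -1.88, interval -2.01 to -1.76). RGS7 (2.67), the glutamate transporter SLC1A1 (2.27), SMAD3, which carries Activin and NODAL signals (2.19), and LINC00458 (1.79) were also higher. NTS (-2.04), the BMP target ID1 (-1.82), MESP1 (-1.68) and the corepressor TLE1 (-1.61) were lower, though free RNA of the BMP4 library, with ID1 at 724 and MESP1 at 169.6 CPM, may add to the BMP4 levels and was not measured in the other libraries. EOMES stood at 404 against 403 and CER1 at 1583 against 1948 CPM. Of 9930 genes, 255 were at least 2-fold higher and 152 lower, and the whole interval lay past 2-fold for 52 and 34. The BMP4 cells of this class held 1421296 UMIs against 5970268, which limits the counts at low levels.

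Epiblast-like cells of the libraries lay in different clusters, with 318, 54 and 337 BMP4 cells, 462, 788 and 18 CHIR cells and 764, 580 and 204 CHIR+Activin cells in clusters 6, 8 and 13. Ratios over the whole class therefore mix clusters, and those within cluster 6, chosen after the data were seen, are given second. The pluripotent epiblast list was lower than in BMP4 under CHIR (median log2 ratio -0.41, percentile 0, and -0.18, percentile 0.07) and under CHIR+Activin (-0.27, percentile 0, and -0.13, percentile 0.31). The same list named these clusters, with 4 members passing in cluster 8 and 10 in cluster 13. The whole-class medians therefore follow in part from where each library's cells lay and test nothing. POU5F1 stood at 1171 against 1169.5 CPM and NANOG at 72.8 against 71.5 CPM under CHIR and BMP4, and at 1221 and 68.3 CPM under CHIR+Activin. FGF8 (log2 ratio 2.81 and 2.59), SP5, a direct WNT target (1.96 and 1.98), CHAC1 (2.02 and 1.55) and DDIT4 (1.78 and 1.38) were higher under CHIR than under BMP4, the last 2 being leading genes of cluster 8. The glutamate receptor gene GRIK2 (-2.56 and -2.07), FOXD3-AS1 (-1.85 and -2.07) and CTNNA2 (-1.48 and -1.11), leading genes of cluster 13, were lower, as were NTS (-1.92 and -2.09) and FOXO1 (-1.49 and -1.22), and free RNA may add to the BMP4 levels here too. At least 2-fold, 67 genes were higher and 90 lower in the class, and 62 and 53 in cluster 6. Under CHIR+Activin against BMP4 the counts were 26 and 19 in the class and 33 and 20 in cluster 6, with PGP (1.37 and 1.37), SP5 (1.35 and 1.19), LINC01356 (1.34 and 1.02) and GLRX5 (1.29 and 1.296) higher and NTS (-1.71 and -1.99), GRIK2 (-1.41 and -1.10) and CTNNA2 (-1.04 and -0.93) lower. Against CHIR they were 4 and 4 in both.

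Streak-like cells of both CHIR libraries, mostly from clusters 4 and 7, differed from those of BMP4, mostly from cluster 2, so the class compares different clusters and rests on the tie-break for cluster 2. FOXA2 (71.7 against 3.44 CPM), LEFTY1 (145 against 19.8 CPM) and FGF8 (97.8 against 16.3 CPM) were higher under CHIR than under BMP4, and MESP1 (0.884 against 149 CPM) and NTS (33.4 against 989.8 CPM) were lower. Within cluster 4 alone, with 833 CHIR and 102 BMP4 cells, the differences were smaller, with FOXA2 at 81.8 against 21.02, LEFTY1 at 132 against 63.1, FGF8 at 90.5 against 28.03, MESP1 at 1.06 against 17.2 and NTS at 27.9 against 178 CPM. FGF8 helped to name cluster 4 and FOXA2 was among its leading genes, so their smaller differences follow in part from the clustering. Free RNA may add to the BMP4 levels here too, in the class and in cluster 4. In the whole class, 149 genes were at least 2-fold higher and 152 lower under CHIR, and 103 and 146 under CHIR+Activin against BMP4. Without the tie-break these counts were 67 and 44, and 54 and 61. Between CHIR+Activin and CHIR, 9 genes were at least 2-fold higher and 2 lower, FGF17 (177 against 87.9 CPM, log2 ratio 1.01) being the single one of at least 50 CPM.

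Cell by cell, TBXT and MESP1 were detected in more BMP4 cells, and SOX2 and FOXA2 in more cells of the CHIR libraries. After thinning to 10000 UMIs per cell, TBXT had a UMI in 71.4% (70.3 to 72.5) of BMP4 cells, 32.2% (31.1 to 33.4) of CHIR and 32.8% (31.6 to 33.98) of CHIR+Activin cells (73.4%, 53.3% and 44.7% unthinned). MIXL1 had a UMI in 73.2%, 61.96% and 56.97% (74.6%, 75.6% and 65.2% unthinned) and EOMES in 60.2%, 43.3% and 43.4% (63.9%, 61.8% and 53.01% unthinned). For comparison, BMP4 cells of the epiblast-like cluster 13 (median 16130 UMIs, library median 12327) had TBXT in 9.43%, MIXL1 in 11.9% and EOMES in 11.9%. In the epiblast-like cluster 8 the shares of TBXT, MIXL1 and EOMES were 14.6%, 32.7% and 19.4% of CHIR cells (median 19256.5 UMIs, library 22295). They were 9.19%, 27.4% and 13.96% of CHIR+Activin cells there (median 15989 UMIs, library 16790). Thinning left out 2350 BMP4, 192 CHIR and 332 CHIR+Activin cells of lower depth.

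MESP1 had a UMI in 54.6% (53.4 to 55.8), 0.541% (0.377 to 0.752) and 2.33% (1.97 to 2.74) of BMP4, CHIR and CHIR+Activin cells (57.7%, 1.71% and 3.78% unthinned), against 4.09% in BMP4 cluster 13, 0.259% in CHIR cluster 8 and 1.06% in CHIR+Activin cluster 8. GATA3 had one in 17.2%, 0.216% and 0.114% (20.99%, 0.601% and 0.279% unthinned), against 0.943% in BMP4 cluster 13 and 0.517% in CHIR cluster 8, so the CHIR share was not above that of its cluster 8. In CHIR+Activin cluster 8, GATA3 had a UMI in 0 of 566 cells, which allows up to 0.530%. SOX17 had one in 14.4% (13.6 to 15.3), 0.0464% (0.00957 to 0.136) and 1.94% (1.61 to 2.32) of BMP4, CHIR and CHIR+Activin cells (15.9%, 0.0751% and 2.40% unthinned), against 0.943% in BMP4 cluster 13 and 0.177% in CHIR+Activin cluster 8. In CHIR cluster 8, SOX17 had a UMI in 0 of 773 cells, which allows up to 0.388%, so SOX17 was not detectable there at this depth, and 21 of the 22 CHIR UMIs of SOX17 came from 4 cells of cluster 14. FOXA2 had one in 2.39% (2.03 to 2.79), 32.4% (31.3 to 33.6) and 24.5% (23.4 to 25.6) of BMP4, CHIR and CHIR+Activin cells (3.12%, 48.7% and 33.3% unthinned), against 0.182% in amnion-like BMP4 cells (median 13587 UMIs), 18.1% in CHIR cluster 8 and 5.97% in CHIR+Activin cluster 13 (median 20708 UMIs). The clusters taken for comparison differ between genes and libraries, and their cells may express the gene. Their shares are therefore no measured background and are not compared between libraries. SOX2 had one in 14.1%, 41.9% and 47.9% (16.2%, 62.7% and 60.7% unthinned), against 2.06% in mesoderm-like BMP4 cells (median 11608 UMIs) and 7.42% in endoderm-like CHIR+Activin cells (median 17324.5 UMIs), while no CHIR cluster was taken for comparison.

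EOMES and TBXT were detected together in 50.5% of BMP4, 17.9% of CHIR and 20.3% of CHIR+Activin cells, where independence would give 43.00%, 13.9% and 14.2%. TBXT and SOX2 were together in 5.95%, 10.7% and 11.2%, where independence would give 10.1%, 13.5% and 15.7%. SOX17 and FOXA2 were together in 0.447% of BMP4 and 0.701% of CHIR+Activin cells, where independence would give 0.345% and 0.476%, and SOX17 was detected in 3 CHIR cells. TBXT with SOX17 (9.43%, 0.0464% and 0.962%), TBXT with TBX6, a factor of paraxial mesoderm (10.02%, 0.448% and 1.06%), and GATA3 with TBXT (10.6%, 0.0619% and 0.0489%) were highest in BMP4, as were the shares of the single genes. Independence would give 10.3%, 0.0150% and 0.636% for the first pair, 8.31%, 0.304% and 0.588% for the second and 12.3%, 0.0698% and 0.0374% for the third.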

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

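Of the tests in this part, the one on shared barcodes was chosen before its result was seen, and those on cell mixture, scaling, carried-over cells, handling, damaged cells and clusters 8, 9 and 10 were chosen only after. The bounds for the last 3 were set again once their values were known, and the streak-like class was taken for the last one then.

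Signal was found in barcodes that no main comparison used, although the looser cell filter took in some of the removed ones. In the BMP4 library, 1592061 barcodes of at most 100 UMIs, too few for a cell, held 1245 UMIs of the mesoderm factor MESP1, above the limit of 3 that a count of 0 allows. These barcodes held 4.95% of the library's UMIs, and 98.97% of 4384 genes in them were within 2-fold of their level in cells, so that MESP1 UMIs were bound to be there as free RNA and are no separate signal. In the CHIR library, the 622 barcodes removed by the cell filter (median 1716 UMIs, 26.8% mitochondrial) held POU5F1 at 247 CPM, and in the CHIR+Activin library the 515 removed barcodes (median 1932 UMIs, 21.1% mitochondrial) held it at 188 CPM, where kept cells had 1043 and 1069 CPM.

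WNT feedback and beta-catenin target genes were lower in CHIR than in BMP4, with a median log2 ratio of -0.84 over 12 members. Scaling of the libraries was excluded, since the higher of the medians under TMM and median-of-ratios scaling was -0.88. Within the epiblast-like class, where most CHIR cells lay in cluster 8 and most BMP4 cells in clusters 6 and 13, the median of the same genes was 0.27, and it was 0.49 within cluster 6 alone and -0.14 within the streak-like class. Over the 6 members of at least 10 CPM in the epiblast-like class the median was 0.34 (percentile 99.85), with AXIN2 at 0.60 and SP5 at 1.96 but BAMBI at -0.53, while the lower LGR5 (6 and 11 UMIs) and NOTUM (23 and 17 UMIs) rested on few counts. Members with many counts went both ways within the streak-like class. BAMBI (-1.85, 514 and 2146 UMIs), TCF7 (-0.79) and LEF1 (-0.68) were lower there, whereas AXIN2 (0.77), SP5 (0.87) and APCDD1 (1.12) were higher. BAMBI is also on the BMP target list, so its lower level need not concern WNT signalling. A candidate explanation is that BMP4 cells of kinds that CHIR colonies lacked carry the list in the whole-library sum, and a lower response of single members in some cells remains open.

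CHIR+Activin held 55 mesoderm-like cells in cluster 1, where CHIR held 0. Of their barcodes, 1.82% (1 of 55, upper limit 9.72%) were also called in BMP4, against 0.186% of all CHIR+Activin cells, which excludes barcodes read in the wrong library as the source of most of these cells. BMP4 cells carried over would bring clusters 2 and 11 along, but these made up 14.1% of the 64 CHIR+Activin cells in clusters 1, 2 and 11 (upper limit 25.02%), against 54.1% in BMP4, which excludes a carry-over in BMP4's own mixture. The cells had ID1 at 121 CPM and LEFTY1 at 70.3 CPM, against 494 and 9.10 CPM in BMP4 cells of the cluster. As a hypothesis, a small number of mesoderm-like cells may have arisen under CHIR+Activin, found and tested on the same data.

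Unfolded protein and integrated stress genes were lower in CHIR+Activin than in CHIR (median log2 ratio -0.29). Within the streak-like class, which holds no cells of clusters 8, 9 and 10, the median was -0.23 (percentile 0, 8 of 10 intervals below 0), which excludes fewer cells in these clusters as the whole cause, and without their cells the library median was -0.17. Handling during dissociation remains open, since the dissociation list had a median of -0.00512 (percentile 80.7) but its members went both ways, with 5 of 12 intervals above 0 and 5 below. Damaged cells also remain open, because the stricter cell filter, with a median of -0.28, moved 0 of 67 list medians and so tested nothing. The treatment, with Activin added and less CHIR99021, remains open and untested as a biological explanation.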

How the results depend on the processing

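The settings without cluster 15, without clusters 8, 9 and 10, with 2-fold or 1.3-fold naming, without the tie-break and with cluster 6 alone for the epiblast-like class were chosen after the data were seen, and the others before. The naming threshold of 1.5-fold was taken after the outcomes of 2, 1.5 and 1.3 were seen, and the tie-break was added because cluster 2 tied. Across all settings, 51 of 66 recomputed counts of genes at least 2-fold apart lay within 1.5 times the reported count, and of 3564 log2 ratios of named genes 3063 stayed within their counting interval, 501 moved out of it and 0 reversed. With no expression filter and with the 50 CPM filter a gene's ratio cannot change, so 324 of 324 ratios stayed in each by design. Likewise, the lower BMP4 floor cannot change a ratio of CHIR+Activin over CHIR. Without clusters 8, 9 and 10, 200 ratios moved and 124 stayed. Of 723 list medians, 546 stayed, 175 moved and 2 reversed. In the single setting without clusters 8, 9 and 10, 40 list medians moved, 1 reversed and 26 stayed. Of 198 class shares 115 stayed, of 756 detection shares 398, of 112 counts within a class 78 and of 448 log2 ratios within a class 208, the rest having moved except 2 that reversed. Both were HPGD within the streak-like class, CHIR+Activin over BMP4, at 0.175 with 1.3-fold naming and without the tie-break, since BMP4 then has cells of clusters 4 and 7 only. Where no cause is named below, the cause was not tested. With 1 library per treatment no replicate could be left out, and depth limits low genes through the floor of 3 counts.

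With no expression filter, which admits genes of few counts, 3421 genes were at least 2-fold higher and 4233 lower in CHIR over BMP4, 3051 and 3501 in CHIR+Activin over BMP4, and 2729 and 2066 in CHIR+Activin over CHIR, and the caudal list of the last pair reversed to a median log2 ratio of -0.095. With the 50 CPM filter, which compares fewer genes, the counts were 89 and 95, 65 and 80, and 4 and 0. Genes lower in CHIR+Activin than in CHIR numbered 1 under TMM, 1 under median-of-ratios scaling and 0 without clusters 8, 9 and 10, where the glycolysis list of that pair reversed to 0.069.

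Class shares that moved out of their counting interval were these, where 0% means that no cluster took the name or that a named one held no cell of the library. At resolution 0.5, the streak-like shares of CHIR and CHIR+Activin were 12.96% and 22.96% and the epiblast-like share in every library was 0%. The endoderm-like share in every library was then 0%. At resolution 2, the mesoderm-like share of BMP4 was 49.3% and the streak-like shares of BMP4, CHIR and CHIR+Activin were 18.4%, 11.04% and 20.7%. Epiblast-like shares of CHIR and CHIR+Activin were then 32.98% and 33.5%, and the endoderm-like share of CHIR+Activin was 5.69%. Amnion-like shares of CHIR and CHIR+Activin were then 0%. With 50 principal components, the mesoderm-like share of BMP4 was 43.7% and the streak-like shares of BMP4, CHIR and CHIR+Activin were 25.04%, 14.9% and 19.7%. Epiblast-like shares of CHIR and CHIR+Activin were then 33.4% and 28.8%, and the endoderm-like shares of BMP4, CHIR and CHIR+Activin were 1.06%, 0.871% and 7.69%. Amnion-like shares of CHIR and CHIR+Activin were then 0%. Thinned before clustering, the mesoderm-like share of BMP4 was 42.9% and the streak-like shares of BMP4, CHIR and CHIR+Activin were 25.4%, 10.5% and 12.3%. Epiblast-like shares of CHIR and CHIR+Activin were then 15.5% and 19.6%, and the endoderm-like shares of BMP4, CHIR and CHIR+Activin were 1.74%, 2.23% and 11.45%. Amnion-like shares of BMP4, CHIR and CHIR+Activin were then 8.86%, 0% and 0%. With the looser cell filter, the streak-like shares of CHIR and CHIR+Activin were 23.6% and 29.8% and the epiblast-like shares of CHIR and CHIR+Activin were 32.6% and 26.7%. With the stricter cell filter, the streak-like shares of BMP4, CHIR and CHIR+Activin were 1.05%, 10.2% and 11.9% and the epiblast-like share of CHIR was 25.1%. The endoderm-like share in every library was then 0%, and the amnion-like shares of CHIR and CHIR+Activin were 0%. With doublets kept, the mesoderm-like share of BMP4 was 40.3% and the streak-like shares of BMP4, CHIR and CHIR+Activin were 26.9%, 5.97% and 11.2%. Epiblast-like shares of BMP4, CHIR and CHIR+Activin were then 5.99%, 1.47% and 8.09%, and the endoderm-like shares of CHIR and CHIR+Activin were 0.720% and 6.41%. With the lower BMP4 floor, the mesoderm-like share of BMP4 was 43.3% and the streak-like shares of BMP4, CHIR and CHIR+Activin were 23.5%, 6.62% and 14.4%. Epiblast-like shares of BMP4, CHIR and CHIR+Activin were then 6.52%, 4.14% and 11.4%. With 2-fold naming, the streak-like share in every library was 0% and the epiblast-like shares of BMP4, CHIR and CHIR+Activin were 3.81%, 0.2703% and 3.16%. With 1.3-fold naming, the streak-like share of BMP4 was 2.01% and the epiblast-like shares of BMP4, CHIR and CHIR+Activin were 12.8%, 64.3% and 57.8%. The endoderm-like share in every library was then 0%. Without the tie-break, the streak-like share of BMP4 was 2.01%. The mesoderm-like and amnion-like classes and the germ cell marker cluster were found in every setting, whereas the streak-like, epiblast-like and endoderm-like classes were not.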

Other observations

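SOX17 was highest in 2 clusters, with different companions. Cluster 11, all of it from BMP4, had SOX17 at 311 CPM with PRDM1 (192 CPM), TFAP2C (151 CPM), NANOS3 (26.1 CPM), NANOG (62.9 CPM) and POU5F1 (976 CPM), genes known from human primordial germ cells, in which SOX2 is low (3.85 CPM here). FOXA2 stood there at 6.82, EOMES at 37.1 and CER1 at 61.4 CPM. The endoderm-like cluster 14 had SOX17 at 249 CPM with FOXA2 at 59.5, EOMES at 400.0 and CER1 at 1617 CPM, while TFAP2C stood at 7.28, NANOS3 at 0.251 and NANOG at 20.1 CPM. SOX17, PRDM1 and TFAP2C are among the genes that set cluster 11 apart and SOX17 and CER1 among those of cluster 14, so these levels describe the clusters and test nothing.

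Cluster 13, the epiblast-like cluster with most epiblast markers, held 337 BMP4, 18 CHIR and 204 CHIR+Activin cells. SOX2 (168 against 165 CPM), NANOG (73.3 against 73.7 CPM) and POU5F1 (1164 against 1101 CPM) in its CHIR+Activin cells were close to those in its BMP4 cells.

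Cluster 15 held 263 cells from all 3 libraries with a median of 5260 UMIs, 7.55% of UMIs from mitochondrially encoded genes and POU5F1 at 124 CPM. In the BMP4 barcodes of at most 100 UMIs, MIXL1 stood at 197 CPM, against 281 CPM in cells, and 98.97% of 4384 genes were within 2-fold of their level in cells. Such free RNA could not be measured in the other libraries, whose matrices hold called cells only.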
